A study of Mus musculus with 46 samples.

How the data were processed

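Single cells from the cochlea of mice at postnatal day 10 were analysed. The animals carried a tamoxifen-inducible Cre recombinase at the Dio2 gene (Dio2-CreERt2) and the Ai6 reporter, which makes a green fluorescent protein in cells where Cre has acted and in their descendants. Per the labels' protocols, cochleae were dissociated with papain, fluorescent cells were picked one by one under a microscope with a suction pipette, and libraries were made with a full-length polyA cDNA kit (SMART-Seq v4) and a DNA library kit (ThruPLEX). Each of the 46 samples is 1 cell.

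Per the submitters' processing notes, bcl2fastq 2 and STAR 2.7.3a were used, with the genome builds GRCm38 and mm10. The program that counted reads per gene, the gene annotation and the use of strand are not given in the sources used here. The values are CPM (reads per 1000000 reads), as deposited by the authors and named so in the file headers, for 29871 genes with their symbols and NCBI Gene identifiers. The listed genes summed to between 86.4% and 93.5% of 1000000 per cell, so the total used by the authors also held reads outside these genes. All 100% of the values above 0 were whole multiples of 1 step per cell, within 0.01 read. The step gave whole reads, 2522853 to 10350249 per cell in the listed genes with a median of 4789573. The libraries carry no molecular identifiers, so reads are not independent molecules. The intervals given below cover counting error only. 25 symbols had been turned into dates by a spreadsheet program. March6 was matched by its gene identifier. Of 359 symbols in the fixed lists, 352 matched by symbol, 6 by identifier and 1 had no row of its own. Bglap, Bglap2 and Bglap3 are near-identical copies, as are Hspa1a and Hspa1b, and their split of reads is uncertain. Genes that overlap an antisense gene cannot be told apart from it without strand.

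The labels give 1 group and name no animal, so the 46 cells were treated as 1 sample. No test between cells was made, and no count test could be run on the recovered reads, because there is no second sample. Differences are described by their size on the log2(CPM + 1) scale, which understates differences of low genes. Standard deviations (SD) are over cells. Shares of cells have exact Clopper-Pearson 95% intervals. Because the cells were picked by hand for fluorescence, these shares describe the picked cells and not the tissue.

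Gene lists, cell type markers, the rule for named genes and the clustering were fixed before the data were examined. Genes at a CPM of at least 1 in at least 5 cells entered, which left 11447. All genes of the fixed lists, 7 mitochondrial genes and 109 ribosomal protein genes were left out of the clustering. The 2000 genes with the largest variance above a lowess trend on the mean were centred and reduced to 10 principal components. Ward clustering was cut at 2 to 6 clusters, and the number with the highest mean silhouette among cuts with at least 3 cells per cluster was taken. Clusters are numbered by size. A cluster was named "X-like" when at least 3 markers of that type lay at least 2 log2 units above all other cells and at a CPM of at least 1 in 50% of its cells, when no other type had as many such markers, and when its top 10 genes by difference held at least 1 marker of that type and no more markers of any other type. This naming rule was written after the clusters had been seen, from markers fixed before. The condition on the top 10 genes was added after a first version had named cluster 5 general fibroblast-like, with 4 of 6 markers and none in the top 10. No doublet caller was run because the cells were picked singly. Cells with markers of different types were counted.

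The size rule counted genes whose mean log2(CPM + 1) differed by at least 2 between classes and which had a CPM of at least 1 in 75% of the cells of the higher class. For this rule each gene was compared between clusters made from the other of 2 random sets of the genes (seed 1). The named genes are the 12 with the largest difference per direction under this rule between the 2 largest clusters (symbols of the Gm, Rik and LOC kinds, symbols turned into dates, mitochondrial and ribosomal protein genes were not ranked), 5 for each further cluster against all other cells, every member of the thyroid hormone lists, and up to 4 members of each other list. The results of 4 listed genes are not reported here, though they stay in the counts of their lists. Cluster 3 was also set against clusters 1 and 2, with 12 and 8 named genes per direction, a comparison added after seeing the data. For gene lists, members at a CPM of at least 1 in 20% of the cells of either class were counted where they differed by at least 1 in either direction. The median difference was ranked among 10000 random lists matched on mean expression in 20 bins. This percentile describes these cells only.

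After the data were seen, a background limit was added. A gene was called above background in a cell at a CPM of at least 1 and at least 2% of its mean over all cells. Counts of cells "above background" use this limit, while Dio2 detection uses the CPM of 1 fixed beforehand.

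The steps were tested on simulated data. In 5 simulated sets the values of each of the 29871 genes were shuffled over cells, 600 genes with a log2 fold of 6 carried 3 classes, and 200 other genes were changed by known folds. A first version without the 600 genes did not recover the classes from each of the 2 gene sets, and they were added for that reason. With them, clustering cut at the true number of 3 classes recovered them with an adjusted Rand index of 1 in each set. Because that number was supplied, this index does not test the choice of the number of clusters. For the comparison of clusters 1 and 2, the size rule recovered 36% of genes changed by a log2 fold of 2, 83.2% at 4, 92.4% at 6 and 96% at 8. It also took in 169 to 188 unchanged genes per set, at most 2 of them with a difference of 5 or more. The changed genes were drawn only from genes at a CPM of at least 1 in most cells. Recovery of genes found in few cells was therefore not tested. Of 200 random lists, 9 fell outside the middle 95% of the percentiles.

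The alternatives tried were other pseudocounts, filters, numbers of variable genes, components and clusters, average linkage on Spearman correlation, k-means, rescaling by median ratios, thinning of reads to 1 depth, subsets of cells and each cell left out in turn. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9. Coordinates are 1-based on GRCm38, from the GENCODE annotation of that build.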

Results

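Gene expression was measured in 46 single fluorescent cells from the cochlea of Dio2-CreERt2:Ai6 mice at postnatal day 10. Dio2 encodes the type 2 deiodinase, the enzyme that converts the prohormone thyroxine into the active thyroid hormone T3. The question was which cochlear cell types express Dio2. Each cell had between 2522853 and 10350249 reads in the listed genes, and between 3351 and 7143 genes at a CPM of at least 1 (median 4996.5). Mitochondrial genes took 0.456% to 2.98% of the total. All cells belong to 1 labelled group with no animal named, so there is no replicate check on any difference between cells.

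The cells were placed in 6 clusters, of which 3 could be named from markers fixed before the data were examined. The mean silhouette rose from 0.197 at 2 clusters to 0.321 at 6, the most that were tried for the choice. At 7 clusters it was 0.347, but the smallest cluster had 2 cells, under the minimum of 3. The largest of the 6 clusters, with 14 cells (30.4% of the 46, exact 95% interval 17.7% to 45.8%), was osteoblast-like. Osteoblasts are the bone-forming cells, and all 9 of their markers passed the naming rule here. Ibsp, which encodes bone sialoprotein, had a median of 19432 CPM in this cluster and was above background in 12 of 14 cells. Alpl, a phosphatase needed for mineral deposition, had a median of 2821 CPM (12 of 14 cells). Among transcription factors of the osteoblast lineage, Sp7 had a median of 879 CPM, Runx2 297 CPM and Dlx5 364 CPM, with Dlx5 above background in 14 of 14 cells. Outside this cluster Ibsp stayed at or below 59.3 CPM.

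**Figure D1:**
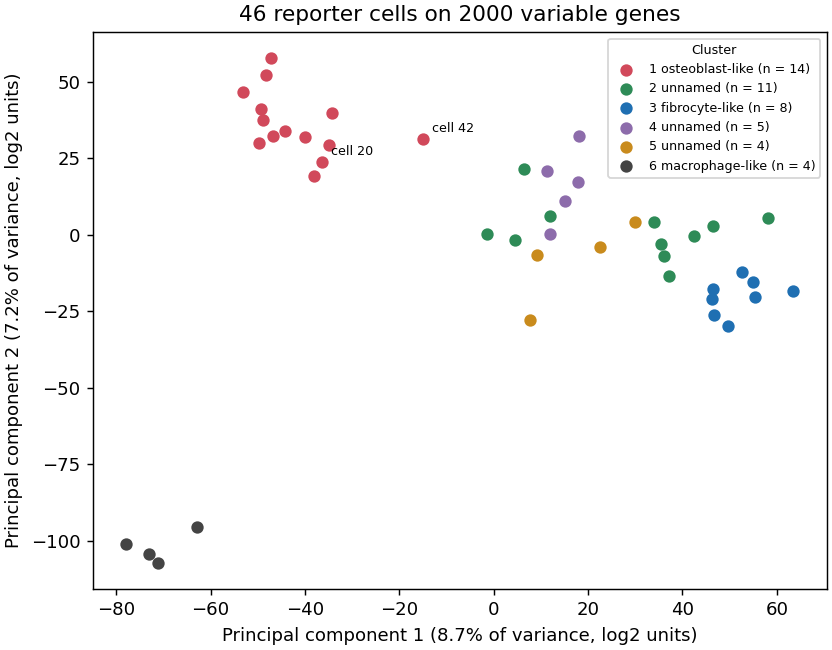
Each point is 1 of the 46 cells on the first 2 principal components of 2000 variable genes, with the share of variance on each axis, coloured by cluster. The 4 macrophage-like cells lie apart at the bottom left, the 14 osteoblast-like cells at the top left, and the 8 fibrocyte-like cells at the right next to cluster 2. Cells 20 and 42 are marked.

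A cluster of 8 cells (17.4%, 7.82% to 31.4%) was cochlear fibrocyte-like. Fibrocytes are the connective tissue cells of the lateral wall and spiral limbus. In this cluster 7 of their 8 markers passed the naming rule. Otos, which encodes otospiralin, had a median of 24838 CPM and Otor a median of 16534 CPM, both above background in all 8 cells. The gap junction genes Gjb2 and Gjb6 had medians of 2387 and 2204 CPM, also in all 8. A macrophage-like cluster of 4 cells (8.70%, 2.42% to 20.8%) passed the rule with 7 of 7 markers, among them the complement genes C1qa, C1qb and C1qc with medians of 2440.4, 3842 and 3891 CPM. Ptprc, the pan-leukocyte marker, was above background in 3 of 4 of these cells.

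Clusters 2, 4 and 5 with 11, 5 and 4 cells kept their numbers. Cluster 2 shared fibrocyte genes with the fibrocyte-like cells but lacked others. Medians were at least 100 CPM for 5 of the 8 fibrocyte markers, including Coch at 12697 CPM, Car3 at 11852 CPM and Otor at 1850.1 CPM, while Otos was above background in 0 of 11 cells and Gjb6 in 2 of 11. The cartilage genes Col9a1 and Lect1 also had high medians there, 3431 and 1263 CPM. These medians did not describe all 11 cells. Car3 was at only 221, 46.8 and 42.9 CPM in cells 22, 38 and 41, and Coch at 54.9 and 367 CPM in cells 38 and 41. Cluster 4 had Pou3f4 (median 343 CPM) and Tbx18 (110.0 CPM) in all 5 cells, without Car3 in any. Cluster 5 mixed markers of several types. Dcn, Lum and Pdgfra, genes of general fibroblasts, had medians of 17269, 7583 and 468 CPM, Gjb2 1856 CPM, and Dmp1, a matrix gene of mature bone cells, 3806 CPM.

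**Figure D2:**
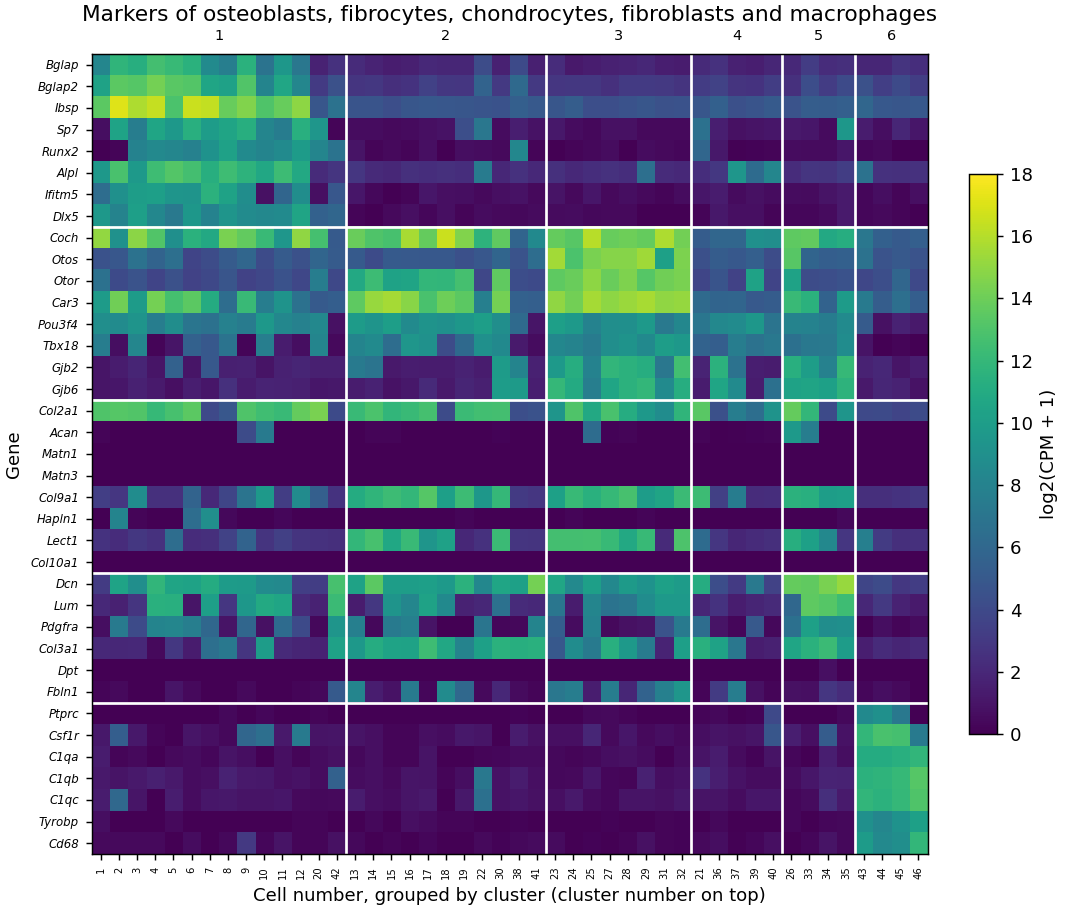
Heat map of log2(CPM + 1) for markers of 5 cell types (rows) in each of the 46 cells (columns), with cells grouped by cluster and white lines between clusters and marker lists. Ibsp fills cluster 1 except cells 20 and 42, Otos and Otor fill cluster 3, C1qa to C1qc fill cluster 6, and Coch spans clusters 1, 2, 3 and 5.

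Several markers were not exclusive to 1 class. Coch, which encodes the matrix protein cochlin and is the classical fibrocyte gene, reached at least 1000 CPM in 10 of 14 osteoblast-like cells (median 5590.3 CPM), and Car3 was above background in 9 of 14 of them. Pou3f4, the transcription factor of otic mesenchyme, was above background in 13 of 14 osteoblast-like, 10 of 11 cluster 2 and 8 of 8 fibrocyte-like cells. Counting cells with at least 3 markers of each type above background, 14 cells held both osteoblast and fibrocyte markers. Fibrocyte and chondrocyte markers were held together by 18 cells. General fibroblast markers were held with fibrocyte markers by 27 cells, the largest overlap, and with osteoblast markers by 8 cells. The limit of 3 markers was reached by 38 cells for fibrocytes, 30 for general fibroblasts, 19 for chondrocytes and 16 for osteoblasts. With totals this large, these overlaps do not by themselves show cells of mixed type. No cell held 3 macrophage markers together with 3 osteoblast or 3 fibrocyte markers. The osteoblast-like cells 20 and 42 had 4 and 3 of the 9 osteoblast markers above background, as did cells 22 and 38 of cluster 2. Cell 20 had Sp7 at 704 CPM and Runx2 at 292 CPM but Ibsp at 27.7 CPM, Alpl at 3.72 CPM and Dmp1 at 21980 CPM. Cell 42 had Runx2 at 114 CPM and Dlx5 at 61.9 CPM with Ibsp at 107 CPM, and 5 of the 6 general fibroblast markers, such as Dcn and Lum, above background. The number of clusters fell to 2 under average linkage on Spearman correlation, and when cell 1, 10, 12, 24 or 29 was left out. The clusters partly followed the numbering of the cells. Cells 1 to 12 were all in cluster 1, cells 13 to 19 in cluster 2 and cells 43 to 46 in cluster 6. What set this order was not known, so an effect of collection order could not be told apart from class.

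Low reads of abundant class markers were present in cells of every other cluster. Over the 13 osteoblast and macrophage markers with a mean of at least 100 CPM, the median CPM in cells outside the class was 0.179% to 0.538% of the mean over all 46 cells. For Ibsp this amounted to 27.5 CPM. Values near this level are not read as expression below.

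**Figure D3:**
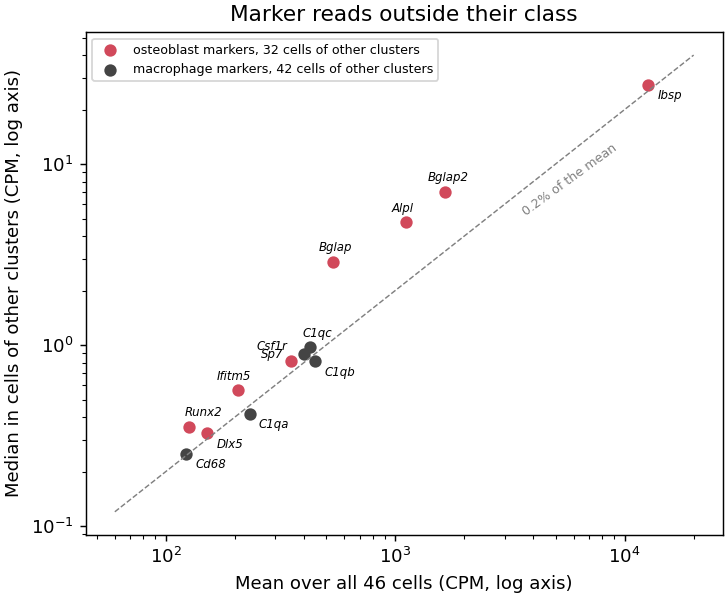
Each point is 1 of the 13 marker genes. The horizontal axis gives its mean over all 46 cells and the vertical axis its median in the cells of other clusters, both in CPM on log axes. The dashed line is 0.2% of the mean, and the points lie along it or up to 0.538% of the mean.

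Dio2 (NCBI Gene 13371, chromosome 12, 90724552 to 90738438, minus strand on GRCm38) was at a CPM of at least 1 in 30 of the 46 cells (65.2%, exact 95% interval 49.8% to 78.6%). At a CPM of at least 100 it was found in 13 cells. At least 1 read was present in 45 cells, which includes values at the background level. The mean over all cells was 84.2 ± 144 CPM (SD, n = 46) and the maximum was 599.8 CPM. Dio2 was detected in 9 of 14 osteoblast-like cells (64.3%, 35.1% to 87.2%), with a mean of 114 ± 148 CPM and a median of 65.5 CPM. In fibrocyte-like cells it was detected in 5 of 8 (62.5%, 24.5% to 91.5%), with a mean of 154 ± 256 and a median of 16.4 CPM. Clusters 2, 4 and 5 had Dio2 in 9 of 11, 4 of 5 and 3 of 4 cells, with means of 44.2 ± 62.6, 84.8 ± 84.4 and 35.3 ± 65.1 CPM. At a CPM of at least 10, Dio2 was found in 9 of 14 osteoblast-like and 4 of 8 fibrocyte-like cells. For clusters 2, 4 and 5 it was found in 6 of 11, 3 of 5 and 1 of 4 cells at that limit. None of the 4 macrophage-like cells reached 1 CPM (exact 95% interval 0% to 60.2%). Their values were 0.194 to 0.465 CPM, which is 1 or 2 reads per cell. With reads thinned to 3522422 per cell in 42 cells, detection was 8 of 12 osteoblast-like, 5 of 8 fibrocyte-like, 10 of 11 cluster 2 and 0 of 4 macrophage-like cells.

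Between the 2 largest clusters, the mean log2(CPM + 1) of Dio2 was 4.68 ± 3.42 (SD, n = 14) in osteoblast-like cells and 3.82 ± 2.57 (SD, n = 11) in cluster 2. The difference of 0.85 was smaller than the pooled SD over cells of 3.08. The difference between clusters 1 and 2 was above 0 in 15 and below 0 in 2 of 17 other settings of the clustering, the scale or the cells used. It ranged from -1.05 to 1.15, and was 2.19 among cells chosen for Dio2 at 1 CPM or more. Against the fibrocyte-like cells the difference was 0.57.

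**Figure D4:**
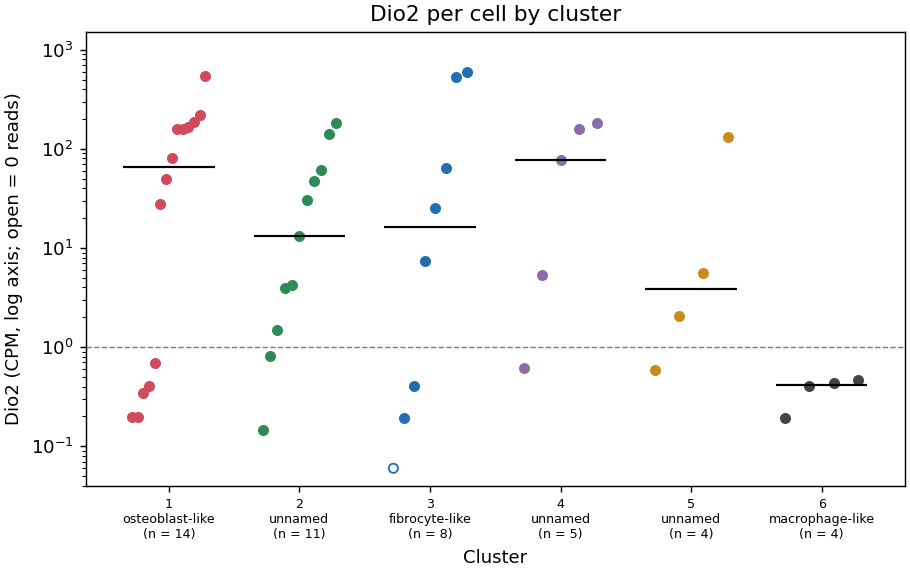
Dio2 in CPM on a log axis for each cell by cluster, with 1 point per cell, a black line at the median of the cluster, a dashed line at 1 CPM and an open circle for the cell with 0 reads. Clusters 1 to 5 each hold cells above and below 1 CPM, and the 4 macrophage-like cells all lie below it.

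Among other genes of thyroid hormone handling, the transporter gene Slco1c1 differed most between osteoblast-like cells and both cluster 2 and the fibrocyte-like cells. Slco1c1 (OATP1C1, which carries thyroxine) was above background in 10 of 11 cluster 2, 8 of 8 fibrocyte-like, 5 of 5 cluster 4 and 4 of 4 cluster 5 cells, with medians of 1295, 1793, 971 and 1387 CPM. It was above background in only 4 of 14 osteoblast-like cells (median 4.37 CPM) and in 0 of 4 macrophage-like cells. The mean log2 difference between osteoblast-like and cluster 2 cells was -5.12. Crym, which encodes a cytosolic T3-binding protein, was above background in 0 of 14 osteoblast-like and 4 of 8 fibrocyte-like cells. The amino acid transporter gene Slc7a8 was above background in all 8 fibrocyte-like and all 4 macrophage-like cells, but in 1 of 14 osteoblast-like cells. Slc7a5 was above background in 4 osteoblast-like cells and no other. Slc16a10 was above background in 6 of 46 cells, 3 of them macrophage-like, and reached 155 CPM in 1 macrophage-like cell. The inactivating deiodinase gene Dio3 was above background in 1 cell, of cluster 2, at 95.9 CPM. Ttr was above background in 1 osteoblast-like cell at 49.3 CPM, and Dio1 had no read in any cell. The fixed list of these 10 genes includes Dio2 itself. Of the 10, 5 could be compared between osteoblast-like and cluster 2 cells, Dio2 (0.85) among them. Of these, 3 were lower in the osteoblast-like cells by at least 1 and 1 was higher. The median difference was -2.19, at percentile 0.0 of the 10000 random lists after rounding.

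The receptor genes were found in scattered cells of each of clusters 1 to 5. Thra was above background in 11 of 14 osteoblast-like, 8 of 11 cluster 2 and 5 of 8 fibrocyte-like cells, and Thrb in 8 of 14, 6 of 11 and 2 of 8. Thrb reached 611 CPM in an osteoblast-like cell and was above background in none of the macrophage-like cells. Thra had log2(CPM + 1) values of 4.01 and 2.01 in the macrophage-like cells 43 and 45. Of the 10 measured receptor and cofactor genes, 2 were higher and 2 lower in osteoblast-like than in cluster 2 cells by at least 1, with 2.92 for Ncor1, 1.41 for Rxrb, -2.39 for Ncoa3 and -1.06 for Ncoa2. Differences for Rxra and Ncoa1 were -0.80 and 0.64. Rxrg and the hepatic response gene Thrsp had no read in any cell. Klf9, a transcription factor gene induced by T3 in many tissues, was above background in 12 of 14 osteoblast-like, 7 of 11 cluster 2, 6 of 8 fibrocyte-like and 0 of 4 macrophage-like cells. Its difference between osteoblast-like and cluster 2 cells was 1.35, and that of Hr was -0.44. With 5000 variable genes the differences of Klf9 and Rxrb turned to -0.47 and -0.36. Among genes of deiodinase protein turnover, Wsb1 was above background in 23 of 46 cells, Usp33 in 14 of 46, March6 in 9 of 46 and Usp20 in 5 of 46.

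**Figure D5:**
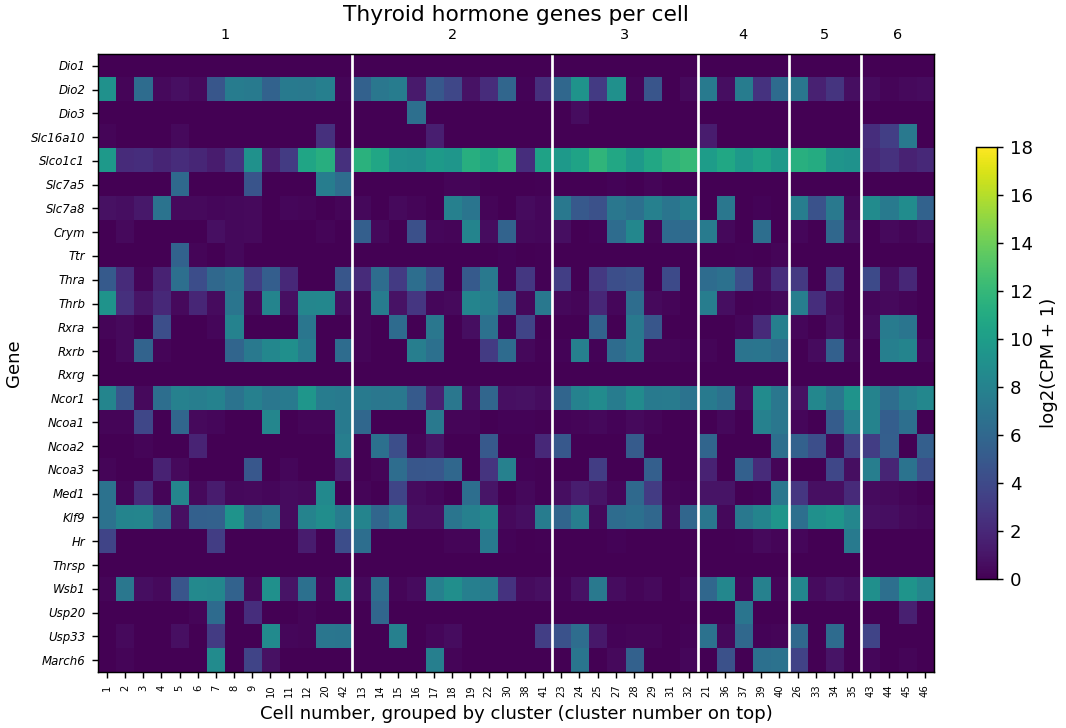
Heat map of log2(CPM + 1) for genes of the 4 thyroid hormone lists (rows) in each of the 46 cells (columns), grouped by cluster. Slco1c1 is high in nearly all cells of clusters 2 to 5 and in 4 of 14 cells of cluster 1, while Dio2, Thra and Thrb are on in some cells of each of clusters 1 to 5 and off in others.

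The largest differences between osteoblast-like cells and cluster 2 included Alpl, Ibsp and Bglap3, genes of bone, on one side and the collagen genes Col8a1, Col9a3 and Col3a1 on the other. With clusters made without the gene, 317 genes were higher in osteoblast-like and 375 higher in cluster 2 cells by at least 2 log2 units. Shuffled values gave 169 to 188 such genes in all, at most 2 of them at 5 or more, against 89 observed at that size. Each gene was shuffled on its own, which removes variation shared between genes. The shuffled counts are therefore not an estimate of false positives among the observed genes. Among genes with a given name, apart from mitochondrial and ribosomal protein genes, the 12 with the largest difference on the osteoblast side were Sgms2 (8.31), Dlx5 (8.22), Alpl (8.03), Panx3 (7.61), Bglap3 (7.41), Ifitm5 (7.20), Smpd3 (7.19), Ibsp (7.02), Tmem119 (6.37), Kcnma1 (6.31), Bglap2 (6.30) and Msn (6.14). On the cluster 2 side they were Col8a1 (-9.31), Col9a3 (-8.15), Col3a1 (-7.62), Ogn (-7.52), Otor (-7.33), Inmt (-7.33), Fmod (-7.30), Phactr1 (-7.28), Itga8 (-7.19), Ntn4 (-7.13), Smoc1 (-7.02) and Col8a2 (-6.73). Of the counted genes, 8 and 21 lay outside this ranking. Dlx5, Alpl, Ifitm5, Ibsp and Bglap2 were among the markers that had named the osteoblast-like cluster. Bglap2 and Bglap3, which encode osteocalcins, share near-identical sequence. The clusterings without the gene placed 3 and 8 of the 46 cells otherwise than the main clusters. With the main clusters used for each gene the counts were 400 and 219. Single differences then changed as well. They were smaller for Col9a3 (-5.43), Otor (-5.17) and Inmt (-5.56), and larger for Ogn (-8.01) and Ibsp (8.795).

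Values for members of lists use the main clusters, so those of Fmod and Smpd3 differ from the ones above. Among the fixed lists, bone mineralization split into opposite directions between these 2 clusters. Of 11 measured members (percentile 91.6), 6 were higher in osteoblast-like cells, including the lipid and phosphate enzymes Smpd3 (6.80) and Phospho1 (4.26), Phex (3.92) and Ank (2.98), which exports the mineral inhibitor pyrophosphate. The other 5 were higher in cluster 2, including Enpp1 (-3.09), which makes pyrophosphate, and Mgp (-2.91), another inhibitor, so inhibitor genes lay on both sides. Of 19 measured genes of bone collagen and its processing, 9 were higher in osteoblast-like and 3 in cluster 2 cells (median 0.73, percentile 91). Col1a1 differed by 4.74, Col5a2 by 4.50, Col5a1 by 4.30 and Bmp1 by 3.14. Other matrix genes went mostly the other way, with 14 of 24 higher in cluster 2 and 5 in osteoblast-like cells (median -1.40, percentile 0.0). Col9a2 differed by -5.92, Fmod by -5.02 and Fn1 by 4.78. Among 8 ion transport genes (percentile 21.6), Gja1 (connexin 43) differed by 5.25, and Aqp1 and Atp1b2 by -4.56 and -4.05.

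FGF and hedgehog genes had 6 of 9 measured members higher in osteoblast-like cells and 1 higher in cluster 2 (median 1.57, percentile 99.6), among them Ptch1 (2.59), Dusp6 (2.49) and Gli3 (2.18). Of 17 Wnt genes, 8 were higher and 5 lower (percentile 90.2, inside the middle 95% of random lists), with 4.91 for Wif1, 4.09 for Lrp4, -3.72 for Dkk3 and -3.06 for Sfrp4. Of 20 BMP and TGF-beta genes, 6 were higher and 6 lower (percentile 60.3), with 4.51 for Bambi, 3.27 for Tgfb1, -3.12 for Id1 and 2.63 for Bmp3. Among 11 IGF and parathyroid hormone genes, 4 were higher and 5 lower (median -0.77, percentile 2). The parathyroid hormone receptor gene Pth1r differed by 4.94, and the binding protein genes Igfbp2, Igfbp6 and Igfbp4 by -6.22, -4.44 and -2.29. Of 25 mesenchymal transcription factor genes, 10 were higher and 6 lower (percentile 52.1), led by Zeb2 (4.80), Sox9 (-4.33), Nfib (3.17) and Dlx6 (2.89). Sox9 is the transcription factor of cartilage. Of 4 genes that act on osteoclasts, 2 were lower in osteoblast-like cells, Cxcl12 (-2.71) and Il34 (-2.21). None of the 8 widely used genes differed by 1.

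The osteoblast-like and fibrocyte-like cells, the 2 largest named classes, were compared in addition. By the size rule 342 genes were higher in the osteoblast-like and 397 in the fibrocyte-like cells. Largest on the fibrocyte side were Fbxo2 (-9.11), Ucma (-8.63), Apod (-8.15), Hhatl (-7.85), Fzd9 (-7.76) and Gjb6 (-7.36), followed by Mrps6, Plekhb1, Psat1, Spint2, Slco1a4 and Aph1a. Slco1a4 encodes another organic anion transporter of the family of Slco1c1 and differed by -7.10. On the osteoblast side the list shared Sgms2, Dlx5, Smpd3, Alpl, Bglap3, Panx3, Tmem119, Ifitm5 and Ibsp with the comparison above, and added Cdh11 (7.03), Col5a1 (6.97) and Fn1 (6.74). All 8 fibrocyte markers were lower in osteoblast-like cells by at least 1, but 7 of them had served to name the fibrocyte-like class, so this largely repeats the naming. Of 19 bone collagen genes, 14 were higher and 2 lower (median 2.19, above all random lists). Of 11 bone mineralization genes, 7 were higher and 2 lower (median 2.01, percentile 99.9). Other matrix genes and the IGF and parathyroid hormone list went the opposite way to the comparison with cluster 2, with 10 of 20 higher and 5 lower (percentile 94.8) and 6 of 11 higher and 2 lower (percentile 97.9). The list of thyroid hormone handling, which includes Dio2, had 6 measured members, of which 3 were lower and 1 higher in osteoblast-like cells (median -2.05, percentile 0.5).

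Cluster 2 and the fibrocyte-like cells were also set against each other. Fst (7.14), Ntn4 (6.83), Fbln5 (6.54), Lox (6.49), Phactr1, Mfap4, Smoc1 and Npnt led on the side of cluster 2. In the main clusters Smoc1 differed by only 3.47, with 5 of 8 fibrocyte-like cells above background, and Mfap4 by 7.785 with 0 of 8. Fbln5, Lox and Mfap4 are genes of elastic fibres. Lrrc8d (-7.40), Otos (-7.06), Ucma, Hhatl, Slc7a8 (-6.55), Slc25a33, Ucp2 and Fzd9 led on the fibrocyte-like side. The size rule counted 301 and 281 genes.

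Against all other cells, the fibrocyte-like cells were led by Ucma (8.19), Fbxo2 (7.47), Hhatl (7.10), Fzd9 (6.93) and Otos (6.80). Cluster 4 was led by Prss23 (7.81), Osr1 (7.56), Dpep1 (7.54), Moxd1 (7.28) and Prss23os (7.09). Prss23os lies opposite to Prss23, and their reads cannot be told apart without strand. Cluster 5 had no counterpart in 1 of the 2 gene sets, so its genes were ranked with the main clusters and are named only to describe it. They were Gpc3, Agt and Cacng4, which helped to define the clusters, and Slc35d3 and Slc16a9, which were not used for clustering. The macrophage-like cells were led by Lyz2 (11.47), Laptm5 (10.99), C1qc (10.95), C1qb (10.93) and C1qa (10.83). Otos for the fibrocyte-like cells and C1qa, C1qb and C1qc for the macrophage-like cells were among the markers that had named these classes.

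Genes induced during dissociation differed between the classes. Of 11 immediate early and stress genes, 10 were higher in osteoblast-like than in fibrocyte-like cells by at least 1 and none was lower (median 2.74, above all random lists). Fos, Egr1, Jun and Ier2 differed by 4.72, 4.50, 3.87 and 3.30. Against cluster 2, 6 of the 11 were higher and none lower (percentile 99.2), with 2.33 for Fos and 1.62 for Egr1. Egr1 had a median of 8585 CPM in macrophage-like and 5.95 CPM in fibrocyte-like cells. Of 12 cell cycle genes, 3 could be compared between osteoblast-like and cluster 2 cells (percentile 74.7). Pcna was above background in 25 of 46 cells and Mcm2 in 10 of 46, but Mki67 in 1 of 46 and Top2a in 3 of 46. No neuronal, hair cell, neutrophil or erythroid list had a member at a CPM of at least 1 in 20% of osteoblast-like or cluster 2 cells.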

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

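The alternatives added after the data were seen were the background limit and thinning for Dio2 detection, the set without cells 20 and 42, clusters 1 and 2 each against cluster 3, the main clusters for every gene, the number of clusters after rescaling, and rescaling with 6 clusters held. The share of cells with Dio2 moved from 65.2% to 97.8% when any read counted, which includes reads at the background level. It was 50% at a CPM of 10 or more, 63.0% above the background limit and 71.4% after thinning. The number of clusters, 6 as reported, was 5 with a pseudocount of 0.1 or 10, with the filter of 10 CPM in 10 cells, in the 30 cells with Dio2 and after thinning. It was 2 under average linkage on Spearman correlation and after rescaling with a new choice of the number, and in both 0 cells were osteoblast-like and 0 fibrocyte-like, because the macrophage-like cells stood against all others. Rescaling with 6 clusters held was chosen after this result had been seen. Leaving out each cell in turn gave 2 to 6 clusters, 6 for 32 of the 46 cells, 5 for 8 cells (16, 17, 20, 23, 33, 34, 37 and 40), 4 for cell 36 and 2 for cells 1, 10, 12, 24 and 29. Over these sets the osteoblast-like class held 0 to 15 cells, the fibrocyte-like class 0 to 15, the macrophage-like class 3 to 4, and the Dio2 difference between clusters 1 and 2 was -0.54 to 1.52 in the 41 sets that kept both. The fibrocyte-like class grew to 20 cells with a pseudocount of 0.1 and to 15 cells with the filter of 10 CPM. The macrophage-like class had 0 cells among those with Dio2 at 1 CPM, by construction. The genes past the size rule, 317 and 375, fell to 109 and 129 with a pseudocount of 10, which shrinks differences of low genes. Those higher in cluster 2 numbered 239 with a pseudocount of 0.1, 206 after rescaling with 6 clusters held and 219 with the main clusters for every gene. The share of genes on each side of this comparison therefore depends on these settings, and the cause was not tested. No filter on low genes and 5 components gave no such count, since 1 of the 2 gene sets lacked a cluster. Of 884 values of 52 named genes under other settings, 865 moved by less than the SD over cells, 17 moved by more, and 2 changed sign after a reported difference of at least 1, Klf9 (-0.47) and Rxrb (-0.36) with 5000 variable genes. For these the cause was not tested. The SD over single cells is wide (3.08 for Dio2), so staying within it is a weak check on a difference of cluster means. Counting differences of any size, 73 values changed sign, among them Dio2 with 5000 variable genes (-1.05) and without cells 20 and 42 (-0.74), both within the SD over cells. Lists were run again under 3 alternatives only, both pseudocounts and the cells with Dio2. Of their 51 medians 2 moved by 1 or more and none outside the middle 95% changed sign, while the lists outside it went from 6 to 5 in each. No paired analysis was possible because there is 1 group.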

Other observations

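All tests below were chosen after the results they concern had been seen, except that of read depth behind missing Dio2 and a first Coch test over clusters 2 and 3 together.

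Some genes were on or off in ways that crossed the classes. Dmp1, a gene of osteocytes and dentin, was above background in 9 of 14 osteoblast-like, 6 of 11 cluster 2 and 4 of 4 cluster 5 cells, with maxima of 21979.5, 23208 and 6047 CPM. Col2a1, the main collagen gene of cartilage, was above background in 11 of 14 osteoblast-like cells at a median of 7657 CPM, while Acan was in 2 of 14 and Matn1 and Col10a1 had no read in any cell. Apoe had a median of 211 CPM in osteoblast-like cells against 7543 in fibrocyte-like and 73980.4 in macrophage-like cells. Slco1c1 was present in 4 osteoblast-like cells, and cell 20, which lacked Ibsp and Alpl above background, was 1 of them at 2507 CPM. The nuclear RNA Malat1 was low, with a median of 22.5 CPM over all cells, and Neat1 was above background in 20 of 46 cells.

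The first pattern is that reads of osteoblast and macrophage markers occur in cells of all other clusters. Over 13 markers with a mean of at least 100 CPM, the off-class median as a share of the mean ranged from 0.179% to 0.538%, a ratio of 3.01 between the highest and the lowest marker. Of 92 values where a background of 0.2% predicts at least 10 reads, 0% were at 0 reads (upper 95% limit 3.93%). On/off transcription was predicted to leave some at 0. Of these values 32 were of Ibsp, 32 of Bglap2, 25 of Alpl and only 1 of a macrophage marker. The values are not independent, and reads in all these cells were the pattern that prompted the test. It therefore cannot decide against transcription in those cells. A constant share of reads passed between the pooled libraries, by index exchange or free RNA, is consistent with both values, and these causes were not separated. The macrophage-like cells held 7 Dio2 reads in all (exact Poisson 95% interval 2.81 to 14.4), and this background predicts 2.87 to 8.62. Their Dio2 reads may thus be background, and why these 4 cells were fluorescent stays open.

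The second pattern is that 16 of the 46 reporter cells had Dio2 below 1 CPM. Among 1238 genes with a mean CPM near that of Dio2, the median gene was at 1 CPM in 58.7% of the cells, and Dio2 at 65.2% lay at percentile 64.1. Dio2 was thus not missed more often than these genes, and loss of transcripts before sequencing may account for it, but bursts of transcription would look alike, and some of these genes may be off in whole classes. Of the 16 cells, 62.5% were among the 23 with the fewest reads, between the limits set beforehand (75% and 60%), so that test left the role of depth open. Detection by cluster after thinning to 1 depth was 8, 10, 5, 4, 3 and 0 cells against 8, 9, 5, 4, 3 and 0 before it. For the 42 cells kept, these counts argue against unequal read depth as the reason for missing Dio2. The 4 cells with the fewest reads were left out of the thinning. A reporter label that outlasts Dio2 transcription is a biological alternative that the design, with 1 group, does not test.

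The third pattern is Coch in osteoblast-like cells. Its median in cluster 1 was 40.5% of the mean over all cells, far above the background of at most 0.538%. RNA taken up from another cell was first tested with 1 limit for both clusters, over 25% of abundant genes under 0.25 of the share that Coch needs, and 22.2% of 81 cluster 2 genes and 37.5% of 72 cluster 3 genes left that test undecided. It was then split by cluster, which argues against cluster 3 RNA, with Otos at 0.172% of its cluster 3 mean where Coch needs 42.5%. For cluster 2 a new test found 6 of 45 genes under 0.25 of the 53.4% needed, such as Col8a1 at 0.42% and Apoe at 6.05%. Col8a1 was at 403 CPM or more in each cluster 2 cell, but at most at 204 CPM in cluster 1. It was above background there in 1 of 14 cells, and so was Ogn, against 11 of 11 cluster 2 cells for both. These values argue against RNA of cluster 2 cells as the source of Coch in most osteoblast-like cells. The median over the 81 abundant genes was 51.7%, near the share needed, but this does not separate uptake from genes expressed in both clusters. Expression of Coch by the osteoblast-like cells themselves is a hypothesis that stays open. Uptake from cells of a type outside these clusters stays open as well, and no biological explanation was tested.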
